A study of Mus musculus with 18 samples.

How the data were processed

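The series comprised 18 libraries from sorted mouse T cells: 12 H3K27me3 ChIP libraries in 6 groups, 5 Foxp3 ChIP libraries from activated Treg cells that form 4 biological replicates, and 1 input library from activated Treg cells. Reads were aligned to mm9, per the labels, with Bowtie 0.12.7, per the submitters' processing notes, and 2 mismatches were allowed, per the series' text file of column descriptions. H3K27me3 regions were built by the authors from 5 kb loci that held over 12 RPM and exceeded input at a Poisson p under 0.001, and were merged within 10 kb where blocks over 8 RPM joined them, per the series' text file of column descriptions, which also says that the union of regions was then used. The deposited H3K27me3 values are log2(RPKM + 0.3), quantile normalized, per the series' text file of column descriptions, and the 12 columns did share 1 distribution. The base of the logarithm was checked on the 578 regions of 5 kb: each must have passed 12 RPM in some library, which is 1.433 on a log2 scale, and their lowest maximum was 1.462. The depth of these libraries is unknown, and a change of the mark over the whole genome is invisible after this normalization.

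Foxp3 sites were called by the authors with SPP, and the deposited Foxp3 values are log2(x + 0.5), per the series' text file of column descriptions. That text names no unit for x and also speaks of quantile normalization, but the columns did not share a distribution. Read as RPM, the values lie on a regular grid of whole reads, and the grid step gave the depth of each column. In sites with up to 15 reads, 100% of values were whole, within the rounding of the printed value. The value of 1 biological replicate pools its technical replicates and was counted once. The Foxp3 table also held 3 columns of libraries from another series, which were not used, so Foxp3 binding in resting cells was not analysed here.

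All 12 H3K27me3 libraries entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, moderated variances with a trend on level, 6 residual and 5.04 prior degrees of freedom). The model shared 1 variance per region over all groups, although the SD of the replicate difference ran from 0.112 in Tn to 0.218 in aTreg. Calls in aTreg can thus be too many and those in Tn too few. Deposited log2 values were used without further scaling, pseudocount or filter. In all, 7 pairs of groups and 2 differences of changes were tested over 4390 regions, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A fold change is on the log2(RPKM + 0.3) scale and so understates changes of low regions. With 2 libraries per group an exact permutation test of 1 region cannot give a p below 0.333, and the labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries. Fitted to simulated data for the aTreg against rTreg comparison, with 200 of 4390 regions changed, the model recovered 12.7%, 70.3% and 97.1% of changes of 0.25, 0.5 and 1 log2 units, and 4.77% of calls were false. The simulated noise was independent between regions and had the same spread in all groups, and no quantile normalization followed. The rates can therefore be worse in the real data. Regions were joined to Foxp3 sites by an overlap of at least 1 base. Sets of regions were tested with camera (preset correlation 0.01), adjusted over the 9 comparisons, and again with an estimated correlation and with fry, which tests a set against no change and not against other regions. Matched draws took 10000 sets of non-overlapping regions with the same spread over bins of level, in a group outside the comparison, and bins of length.

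Comparisons, tests, the rule for named regions and most alternatives were set before the data were examined. The rule took, per comparison, the 10 regions with the largest change in each direction among those past the threshold with both libraries of one group above both of the other, and in each gene list up to 4 members with the lowest p; this last part was carried over to the Foxp3-overlapping set. The text gives a selection of these, and the Foxp3 sites and the examples of regions shared by several groups were chosen after their values were seen. In addition, 16 genes and 14 gene lists (among them Treg signature, naive genes, cytokines, lineage regulators, T cell receptor signalling, homing, Polycomb targets and machinery, and markers of other cell types) had been fixed. They could not be tested, because the files give mm9 coordinates without gene names and the annotation at hand was of GRCm38; regions are therefore given by position and not by gene. Alternatives were a pseudocount of 1.5, leaving out the lowest 25% of regions, no variance trend, median centring, cyclic loess, only the libraries compared, a replicate block, each library left out, a threshold of 0.1, a stricter overlap, and the top 50% of Foxp3 signal. Robust variance, autosomes alone, dropping regions with a mean log2 above 4, distance bins and the matched draws were added after the data were seen. What 2 kinds of draws would show was written down before their values were seen. These were the draws matched on the Tn level (aTreg against rTreg) and on the Treg change (Foxp3-null cells). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.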

Results

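Foxp3 binding and the repressive histone mark H3K27me3 were profiled by ChIP-seq in T cells sorted from the lymph nodes and spleen of mice about 8 weeks old. Foxp3 is the transcription factor that defines regulatory T (Treg) cells, and H3K27me3 is the mark laid down by Polycomb repressive complex 2. H3K27me3 was measured in 6 cell groups with 2 libraries each: activated Treg cells (aTreg), resting Treg cells (rTreg), effector T cells (Teff), naive T cells (Tn), and cells that carry the Foxp3GFPKO allele from males (aFoxp3GFPKO) or from heterozygous females (Foxp3GFPKO). In the Foxp3GFPKO allele a GFP reporter replaces functional Foxp3, so GFP-positive cells have the locus switched on but lack the protein. The table held 4390 broad regions with a median length of 15 kb, from 5 to 445 kb, covering 86.8 Mb. Depth of the H3K27me3 libraries was unknown, because each library had been forced to 1 shared distribution of values. Replicates ranked the regions alike, with Spearman correlations across regions from 0.85 in aTreg to 0.96 in Tn. Between groups, aTreg stood closer to Teff (0.75) than to rTreg (0.45), and rTreg stood close to Tn (0.85).

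The authors' list held 2885 Foxp3 sites of 200 bp, which were read in 4 biological replicates of activated Treg cells beside 1 input library. The median site lay 1.66 log2 units above input, and 2730 sites (94.6%) were above input in all 4 replicates. Because the sites had been called as enriched, these values are no independent evidence of occupancy. The strongest site, on chromosome 7 at 26052483-26052683 (mm9), averaged 3.20 ± 0.814 (SD, n = 4) on the log2 scale, or 10 ± 7.03 RPM (reads per 1e+06 aligned) against 0.18 in input. A site on chromosome 2 at 151566970-151567170 was nearly as strong and far less variable, at 3.11 ± 0.2. Replicates 1 to 4 held 3.70 M, 7.33 M, 9.13 M and 8.45 M reads and the input 21.9 M, so that a median site rested on 6 to 13 ChIP reads. The height of enrichment differed between replicates, with medians over input of 2.65, 1.07, 1.48 and 1.59, and the ranking of sites was shared by replicates 1 and 3 (Spearman 0.63) but hardly by replicates 1 and 4 (0.05). Input had no replicate, so these differences carried no test.

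Most Foxp3 sites lay outside H3K27me3 regions. Of the 2885 sites, 131 (4.54%) fell within 109 of the 4390 regions (2.48%), and 17 regions held more than 1 site, up to 6. All 4390 regions covered 86.8 Mb. The share of sites by chance was not worked out, so avoidance of the mark was not tested. These 109 regions, called Foxp3-overlapping regions from here on, had a median length of 25 kb against 15 kb elsewhere, and 0 of them lay on the X chromosome. They carried less H3K27me3 than other regions in all groups but aTreg. Their median was 1.17 ± 0.01 (SD, n = 2) in rTreg, 1.14 ± 0.01 in Tn and 1.09 ± 0.00 in Foxp3GFPKO, while other regions sat at 1.49 to 1.50 in every group. It reached 1.33 ± 0.01 in Teff and 1.28 ± 0.01 in aFoxp3GFPKO, and 1.50 ± 0.01 in aTreg.

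**Figure D1:**
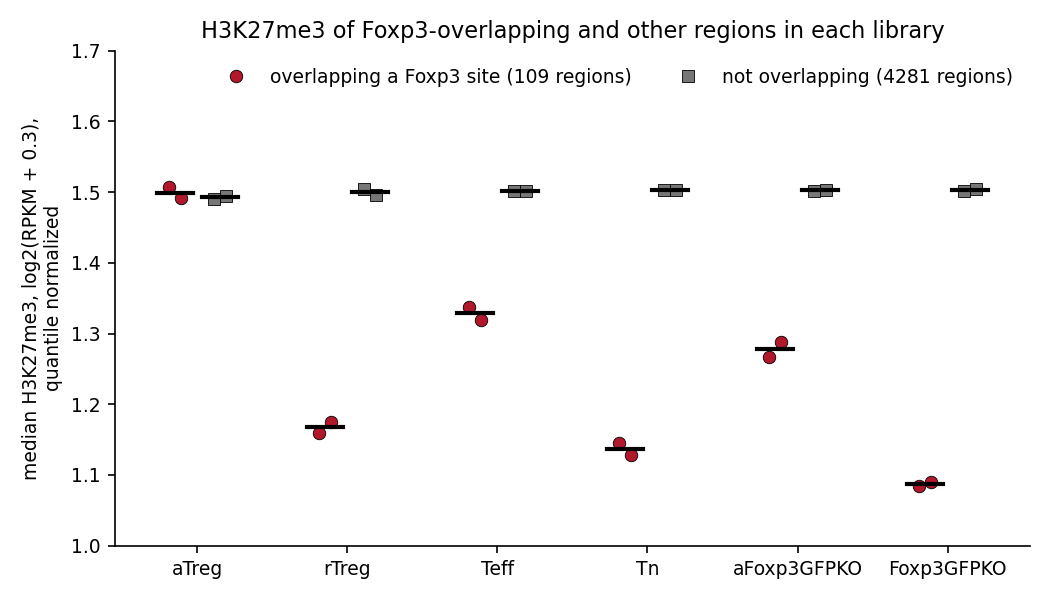
Median H3K27me3 level, as quantile normalized log2(RPKM + 0.3), of the 109 Foxp3-overlapping regions and the 4281 other regions in each library of the 6 groups. Points are libraries and bars are means of 2 libraries; in aTreg the overlapping regions reached 1.50, the level of the other regions, and in the remaining groups they lay between 1.09 and 1.33.

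Activated and resting Treg cells were compared to ask where the mark moves when Treg cells become activated. Foxp3-overlapping regions gained H3K27me3: their median change was 0.44 log2 units, and 71 of the 109 were higher in aTreg, 12 were lower and 26 passed in neither direction. The region with the most sites, on chromosome 11 at 52070001-52140001 with 6 sites, was 1.73 ± 0.03 (SD, n = 2) in aTreg and 0.39 ± 0.03 in rTreg. A region on chromosome 13 at 43865001-43885001 rose from 0.39 ± 0.02 to 1.72 ± 0.04, and one on chromosome 4 at 32305001-32355001 with 2 sites rose from 0.60 ± 0.01 to 1.90 ± 0.00. Regions on chromosome 15 at 88960001-88980001, on chromosome 6 at 94625001-94655001 and on chromosome 18 at 68345001-68360001, each with 1 site, gained 1.52, 1.16 and 1.10. Among other regions 25.6% were higher, against 65.1% of the Foxp3-overlapping ones (Fisher's exact test, two-sided, adjusted p = 3.33e-17 over the 9 comparisons). That test takes regions as independent, but regions within 50 kb changed together (r = 0.55), so its p-values here and below can be too small. The set test (camera, with a preset correlation) gave an adjusted p of 2.57e-10 for the overlapping regions, and an adjusted p of 0.00757 with an estimated correlation; adjusted over the list alone, 72 were higher and 13 lower. The excess over other regions was 0.44 as deposited and 0.22 with cyclic loess (adjusted p = 6.76e-05).

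The gain was largest in overlapping regions that carried little mark. In the 59 overlapping regions from the lowest 25% of mean levels the median change was 0.73, against 0.20 in other regions with such levels, and in the remaining 50 it was 0.14 against -0.06. Non-overlapping regions drawn to match the overlapping ones in Tn level and length had a median change of 0.21, with 95% of 10000 draws between 0.14 and 0.28 and 0 draws as high as 0.44. Foxp3 signal within the overlapping regions did not track the change (Spearman 0.05 across regions, adjusted permutation p = 0.79). Since replicates shared the ranking of sites only in part, a link with binding strength could have been missed. The 28 regions in the top 25% of Foxp3 signal changed by a median of 0.56 (camera adjusted p = 0.000309), and their call was lost with an estimated correlation (adjusted p = 0.0685). It was also lost without the lowest 25% of regions, where their excess over non-overlapping regions went from 0.56 (camera adjusted p = 0.000212) to 0.05 (adjusted p = 0.305).

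**Figure D2:**
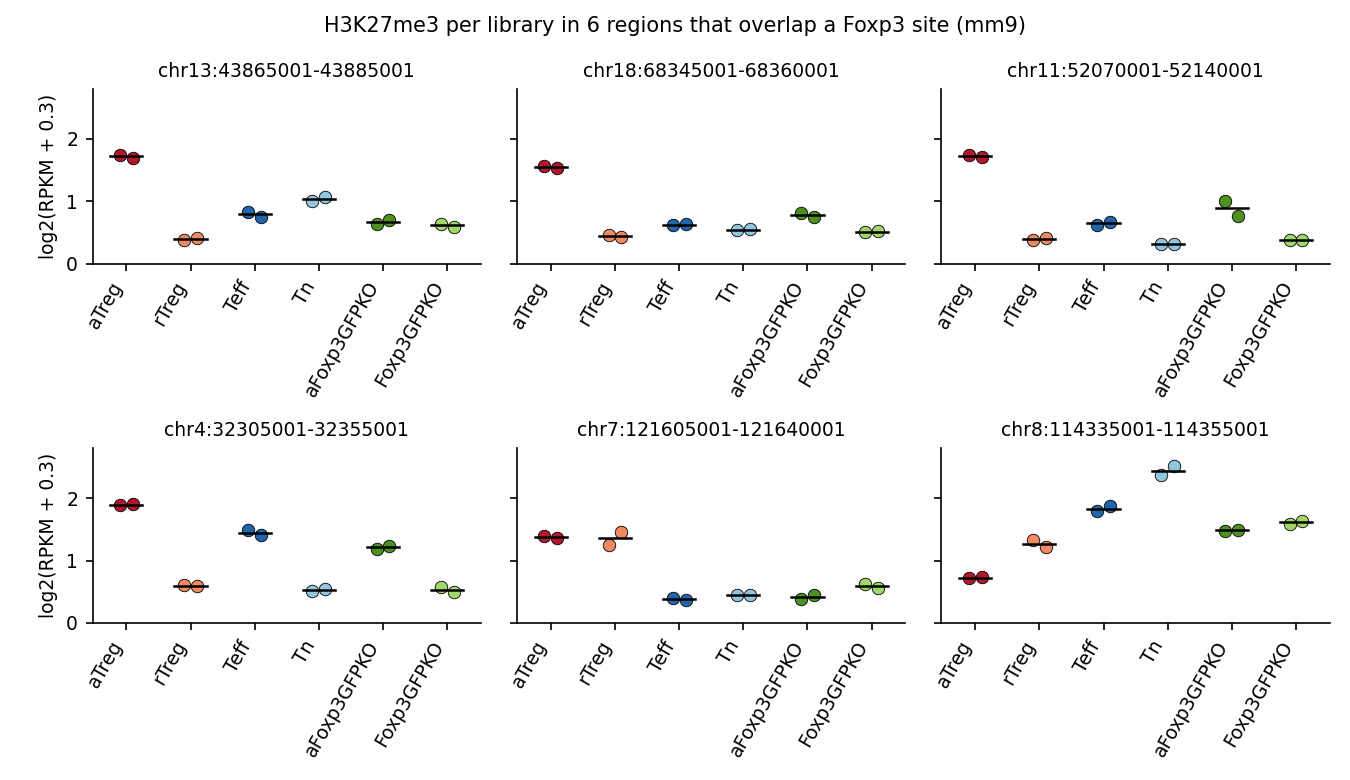
H3K27me3 level as log2(RPKM + 0.3) in each library for 6 regions that overlap a Foxp3 site, named by mm9 coordinates; points are libraries and bars are means of 2 libraries. In the first 4 regions aTreg was highest, the region on chromosome 7 was high in both Treg groups, and the region on chromosome 8 was highest in Tn.

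Across all regions, activation of Treg cells moved H3K27me3 at 2363 of 4390, of which 1166 were higher in aTreg and 1197 lower (limma, adjusted p under 0.05), while 69 moved by at least 1 log2 unit. Outside the Foxp3-overlapping set, a region on chromosome 4 at 101025001-101030001 rose from 0.53 ± 0.13 to 2.10 ± 0.07, and one on chromosome 6 at 120440001-120450001 from 0.61 ± 0.02 to 1.91 ± 0.10. Losses were led by regions on chromosome 11 at 3030001-3100001 (log2 change -4.16, SE 0.23, limma adjusted p = 2.11e-06) and chromosome 18 at 3005001-3010001 (-1.84, SE 0.19), which lie near the start of their chromosomes and carried very high values in most groups. A region on chromosome 10 at 57160001-57165001 fell from 2.67 ± 0.24 to 1.04 ± 0.06, and regions on chromosome 4 at 14755001-14760001 and 88295001-88300001 changed by -1.19 and -1.18. The largest rise, 3.58 (SE 0.47) on chromosome 10 at 126960001-126975001, rested on aTreg libraries that differed widely (6.76 ± 1.38). The median change went from 0.13 in regions of 5 kb, of which 31.8% were higher and 13.5% lower, to -0.22 in regions over 50 kb, of which 12% were higher and 49.1% lower; breadth was not tested. With each library held to the same distribution, a rise or fall of the whole mark could not be seen, and higher and lower calls had to be near balance. Without the lowest 25% of regions 1572 passed, 629 higher and 943 lower.

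**Figure D3:**
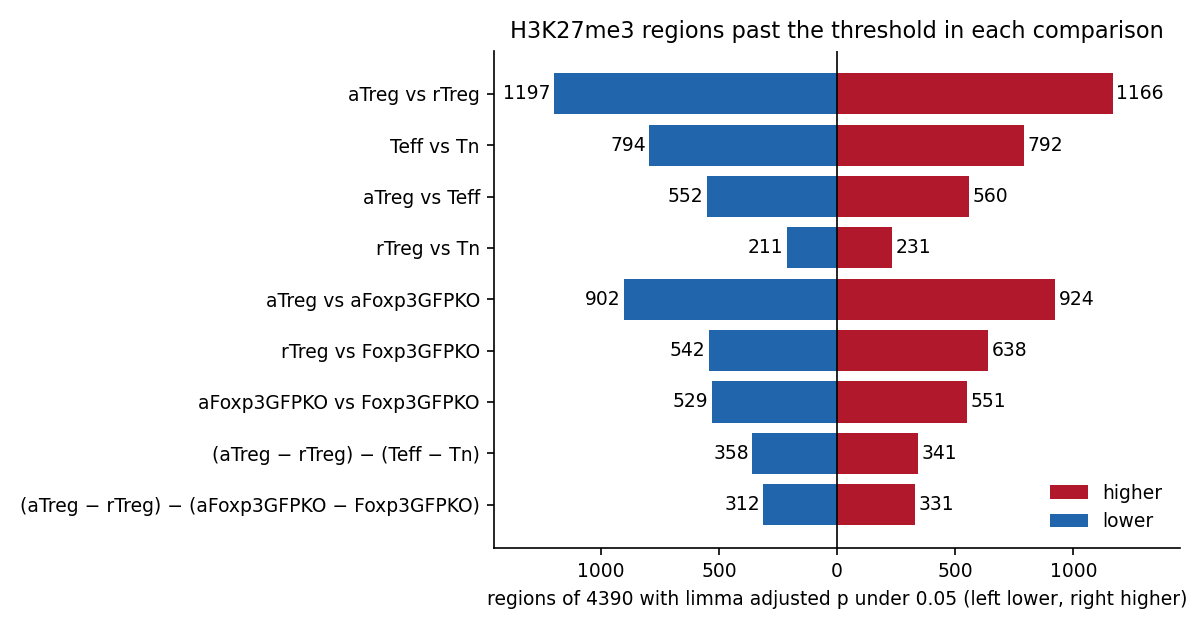
Number of the 4390 H3K27me3 regions with a limma adjusted p under 0.05 in each of the 9 comparisons, higher in the first-named group to the right and lower to the left. The aTreg against rTreg comparison had 1166 higher and 1197 lower.

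Effector and naive T cells were compared to see what activation does to the mark in T cells that do not use Foxp3. Among the strongest gains were those on chromosome 3 at 130800001-130815001, a Foxp3-overlapping region that went from 1.19 ± 0.02 (SD, n = 2) in Tn to 2.54 ± 0.04 in Teff, and on chromosome 2 at 59955001-59970001, from 0.95 ± 0.05 to 2.13 ± 0.01. Teff lost the mark on chromosome 3 at 79330001-79350001 (1.88 ± 0.05 to 0.77 ± 0.03), on chromosome 8 at 118225001-118230001 (1.88 ± 0.22 to 0.83 ± 0.01) and on chromosome 7 at 31380001-31385001 (1.66 ± 0.15 to 0.58 ± 0.12). In total 1586 regions differed, 792 higher and 794 lower in Teff (limma, adjusted p under 0.05). Of the Foxp3-overlapping regions 37 were higher and 17 lower, with a median change of 0.08, among them the regions on chromosome 4 at 32305001-32355001 (0.92) and chromosome 6 at 94625001-94655001 (0.78) that had also risen in aTreg. The set passed with the preset correlation (camera adjusted p = 0.00223) but not with an estimated one (adjusted p = 0.0705), and 12.84% of matched draws had a median as high. Without the lowest 25% of regions its excess was 0.21 (adjusted p = 0.0369), against 0.09 with all regions. Leaving out Tn replicate 1 gave 863 regions, Tn replicate 2 914, Teff replicate 1 1009 and Teff replicate 2 1018.

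Treg activation and T cell activation shared much of their course. Across regions, the aTreg minus rTreg change correlated with the Teff minus Tn change at r = 0.62, and 491 regions were higher in both (210 for independent lists), 580 lower in both (216 for independent lists) and 49 opposite; the comparisons use different libraries, and regions are not independent replicates. The Foxp3-overlapping regions stood out in the difference between the changes, (aTreg - rTreg) - (Teff - Tn), with a median of 0.19; 42 were higher, 8 lower and 59 passed in neither direction (camera adjusted p = 3.43e-09, with an estimated correlation adjusted p = 0.00757). The region on chromosome 13 at 43865001-43885001 had the largest such difference among them (1.57, SE 0.10, limma adjusted p = 2.06e-05), since it rose in Treg cells and stood at 1.04 ± 0.05 in Tn and 0.79 ± 0.06 in Teff. Regions on chromosome 15 at 88960001-88980001, chromosome 12 at 109835001-109900001, chromosome 18 at 68345001-68360001 and chromosome 9 at 60815001-60855001 had differences of 1.33, 1.17, 1.02 and 0.96. In the other direction, neighbouring regions on chromosome 3 at 106005001-106035001 and 105950001-105975001 both differed by -1.33, falling from 1.99 in rTreg to about 0.85 and 0.86 in aTreg. Over all regions 699 differed, 341 higher and 358 lower; without Tn replicate 1 or 2 the count was 309 and 258, without rTreg replicate 2 it was 415, and without either Teff replicate it was 384. Without the lowest 25% of regions 372 differed, 99 higher and 273 lower, and the excess of the overlapping set over other regions went from 0.21 to 0.05 and no longer passed (adjusted p = 0.0906), while with cyclic loess it was 0.07 (adjusted p = 0.00778).

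Male aFoxp3GFPKO and heterozygous female Foxp3GFPKO cells have switched the Foxp3 locus on but lack the protein. They were compared as the nearest match to an activation step in such cells, called Foxp3-null activation below. In heterozygous females such cells live beside functional Treg cells, while males have none and develop systemic inflammation. Foxp3-overlapping regions gained the mark here too: the median change was 0.21, with 44 higher, 8 lower and 57 in neither direction (camera adjusted p = 7.61e-08, with an estimated correlation adjusted p = 0.00908). Examples were chromosome 4 at 32305001-32355001 (0.53 ± 0.06 to 1.21 ± 0.03, SD, n = 2), chromosome 9 at 60815001-60855001 (0.72 ± 0.05 to 1.35 ± 0.03), chromosome 9 at 68870001-68890001 (0.68 ± 0.00 to 1.43 ± 0.08) and chromosome 2 at 162990001-163130001 (0.96 ± 0.01 to 1.46 ± 0.02). Elsewhere, chromosome 7 at 150925001-150930001 and chromosome 11 at 75005001-75015001 rose by 1.11 and 0.98, and chromosome 13 at 3370001-3375001 and chromosome 7 at 3410001-3415001 changed by -1.24 and -1.09. Altogether 1080 regions differed, 551 higher and 529 lower (limma, adjusted p under 0.05). These groups differed in sex as well as in setting, and only a title that starts with a marks the male cells as activated. The comparison alone therefore could not separate the effects. Without Foxp3GFPKO replicate 1 the number of regions was 416, without aFoxp3GFPKO replicate 1 it was 514, and with only the libraries of these groups it was 407.

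The gain of Foxp3-overlapping regions was larger in Treg cells than in Foxp3-null cells. The difference (aTreg - rTreg) - (aFoxp3GFPKO - Foxp3GFPKO) had a median of 0.27 over the 109 regions, with 42 higher and 4 lower (camera adjusted p = 7.19e-09, with an estimated correlation adjusted p = 0.00757). It was 1.27 on chromosome 13 at 43865001-43885001, 0.83 on chromosome 18 at 68345001-68360001, 0.97 on chromosome 12 at 109835001-109900001 and 0.69 on chromosome 4 at 32250001-32300001. The 59 overlapping regions from the lowest 25% of levels had a median difference of 0.49, and the other 50 of 0.01. Among all regions 643 differed, 331 higher and 312 lower (limma, adjusted p under 0.05), and 302, 107 higher and 195 lower, without the lowest 25%, where the overlapping set no longer passed (excess 0.06, adjusted p = 0.104). With cyclic loess its excess was 0.08 (adjusted p = 0.0172), against 0.28 as deposited. Without Foxp3GFPKO replicate 2 261 regions passed, and without rTreg replicate 1 or 2 385 and 354 did.

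Activated Treg cells were set against aFoxp3GFPKO cells, which lack Foxp3 protein. The Foxp3-null cells came from males without functional Treg cells, and the labels give neither sex nor strain for the aTreg donors. The comparison alone therefore could not separate Foxp3 protein from sex, strain or surroundings. Foxp3-overlapping regions carried more H3K27me3 in aTreg, by a median of 0.29, with 60 higher, 5 lower and 44 in neither direction (camera adjusted p = 2.57e-10, with an estimated correlation adjusted p = 0.00757); of other regions 20.2% were higher. The regions on chromosome 13 at 43865001-43885001 (1.72 ± 0.04 in aTreg, 0.67 ± 0.04 in aFoxp3GFPKO, SD, n = 2), chromosome 7 at 121605001-121640001 (1.37 ± 0.03 and 0.42 ± 0.05), chromosome 2 at 57075001-57100001 (1.63 ± 0.01 and 0.68 ± 0.12) and chromosome 18 at 68345001-68360001 (1.55 ± 0.03 and 0.79 ± 0.05) had the lowest p among them. A non-overlapping region on chromosome 5 at 107715001-107725001 was also high in aTreg (1.76 ± 0.15 against 0.57 ± 0.05). Regions much higher in the Foxp3-null cells lay on the X chromosome at 166410001-166435001 (3.38 ± 0.41 against 1.00 ± 0.10), on chromosome 1 at 90100001-90165001 (3.16 ± 0.44 against 0.99 ± 0.01) and on chromosome 17 at 13735001-13745001 (2.60 ± 0.57 against 0.46 ± 0.08). In female Foxp3GFPKO cells they stood at 2.69 ± 0.92, 2.52 ± 0.41 and 1.74 ± 0.28, also above aTreg. In total 1826 regions differed, 924 higher and 902 lower in aTreg (limma, adjusted p under 0.05), and 1198 when only these groups' libraries entered the fit. Without the lowest 25% of regions 482 were higher and 725 lower, and with cyclic loess the excess of the overlapping set was 0.13 (adjusted p = 0.00216).

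Between resting Treg cells and female Foxp3GFPKO cells the Foxp3-overlapping set did not pass with camera. Its median difference was 0.01, 20 regions being higher in rTreg, 6 lower and 83 in neither direction (camera adjusted p = 0.261, fry adjusted p = 0.0158). The median was -0.02 in the 59 low regions and 0.12 in the other 50, and without the lowest 25% of regions the excess was 0.14 (adjusted p = 0.0546). A few members stood apart, such as those on chromosome 13 at 18035001-18080001 (2.45 ± 0.00 in rTreg, 1.59 ± 0.13 in Foxp3GFPKO, SD, n = 2) and chromosome 7 at 121605001-121640001 (1.35 ± 0.15 and 0.59 ± 0.05). Across all regions 1180 differed, 638 higher and 542 lower in rTreg (limma, adjusted p under 0.05). The mark was higher in rTreg on chromosome 2 at 61640001-61675001 (3.35 ± 0.09 against 2.02 ± 0.34), 44955001-44975001 (2.76 ± 0.03 against 1.50 ± 0.08) and 18610001-18635001 (3.07 ± 0.06 against 1.87 ± 0.03), and lower on chromosome 6 at 94230001-94235001 (1.25 ± 0.02 against 2.52 ± 0.08). Broad regions leaned towards rTreg, 27.3% of those over 50 kb being higher and 8.8% lower. With only these libraries in the fit 662 regions passed, and without Foxp3GFPKO replicate 2 588 did.

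Activated Treg cells and effector T cells, both antigen-experienced, differed at 1112 regions, 560 higher and 552 lower in aTreg (limma, adjusted p under 0.05). Foxp3-overlapping regions were higher in aTreg by a median of 0.22, with 50 higher, 16 lower and 43 in neither direction (camera adjusted p = 3.43e-09, with an estimated correlation adjusted p = 0.00757). The region on chromosome 1 at 36350001-36365001 with 2 sites stood at 1.91 ± 0.15 (SD, n = 2) in aTreg and 0.76 ± 0.06 in Teff, and that on chromosome 9 at 60815001-60855001 at 1.66 ± 0.00 and 0.76 ± 0.04. The Foxp3-overlapping region on chromosome 8 at 114335001-114355001 went the other way (0.73 ± 0.01 and 1.83 ± 0.06). Teff carried more of the mark on chromosome 3 at 130685001-130720001 (2.08 ± 0.04 against 0.80 ± 0.07) and chromosome 4 at 46595001-46620001 (1.59 ± 0.05 against 0.36 ± 0.02). Without the lowest 25% of regions 517 passed, 160 higher and 357 lower, and the overlapping set did not pass (excess 0.14, adjusted p = 0.107), while with cyclic loess its excess was 0.12 (adjusted p = 0.0164), against 0.25 as deposited; with only these libraries 653 passed, and without Teff replicate 1 or 2 624 and 626.

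Between resting Treg and naive T cells 442 regions passed the threshold, 231 higher and 211 lower in rTreg (limma, adjusted p under 0.05). Foxp3-overlapping regions showed no common direction, the median being 0.01 with 12 higher, 14 lower and 83 in neither direction (camera adjusted p = 0.504). They held changes in both directions more often than other regions: 12.8% were lower against 4.6% (Fisher's exact test, two-sided, adjusted p = 0.00189), and 11% were higher against 5.12% (adjusted p = 0.0156). Treg cells carried more of the mark on chromosome 7 at 121555001-121570001 (1.55 ± 0.11 against 0.60 ± 0.03, SD, n = 2) and 121605001-121640001 (1.35 ± 0.15 against 0.45 ± 0.01) and on chromosome 13 at 18035001-18080001 (2.45 ± 0.00 against 1.47 ± 0.02). They carried less on chromosome 4 at 46595001-46620001 (0.57 ± 0.06 against 1.79 ± 0.12), chromosome 8 at 114335001-114355001 (1.27 ± 0.09 against 2.44 ± 0.10), chromosome 1 at 155155001-155190001 (1.28 ± 0.00 against 2.43 ± 0.02) and chromosome 5 at 143835001-143930001 (1.65 ± 0.04 against 2.48 ± 0.00). The count rested on few libraries: without Tn replicate 1 it was 94, 35 higher and 59 lower, without Tn replicate 2 it was 72, 22 higher and 50 lower, and without rTreg replicate 1 or 2 it was 229 and 126.

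Distance from a Foxp3 site was followed in 4 comparisons. In aTreg against rTreg the median change fell from 0.44 in overlapping regions (95% bootstrap interval over regions 0.28 to 0.63) to 0.23 (0.13 to 0.30) within 10 kb, 0.12 (0.09 to 0.15) from 10 to 100 kb, -0.05 (-0.08 to -0.04) from 100 kb to 1 Mb and -0.10 (-0.14 to -0.04) beyond 1 Mb. In aTreg against aFoxp3GFPKO the medians were 0.29, 0.15, 0.06, -0.04 and -0.03 over the same distances. In aFoxp3GFPKO against Foxp3GFPKO only the overlapping regions stood clear of 0.05, at 0.21, followed by 0.01, 0.03, -0.04 and -0.03, and in Teff against Tn they were 0.08, 0.02, 0.03, -0.04 and -0.01.

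**Figure D4:**
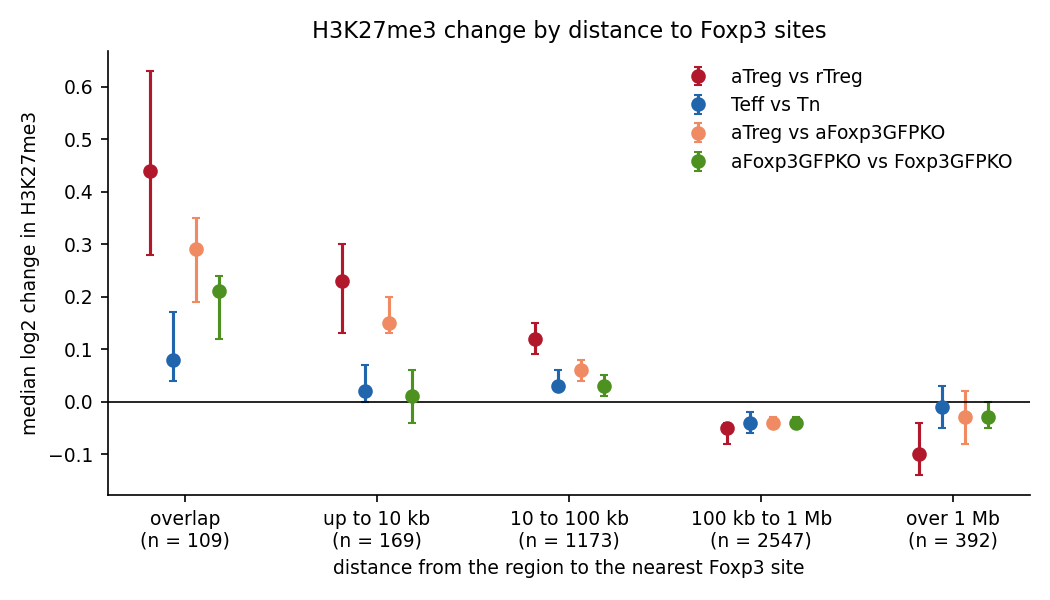
Median log2 change in H3K27me3 by distance from the region to the nearest Foxp3 site, for 4 comparisons; points are medians over regions, error bars are 95% bootstrap intervals over regions, and the number of regions is under each distance. The aTreg against rTreg median fell from 0.44 in overlapping regions to -0.10 beyond 1 Mb.

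The X chromosome was followed separately because the inactive X of females is rich in H3K27me3 and the labels give the Foxp3-null groups different sexes. Over its 28 regions the median level was 1.56 ± 0.00 (SD, n = 2) in female Foxp3GFPKO cells and 1.18 ± 0.20 in male aFoxp3GFPKO cells, 25 of 28 regions being lower in males with a median change of -0.33 (camera adjusted p = 2.21e-06, with an estimated correlation adjusted p = 0.0386). The labels gave no sex for the remaining groups, whose X medians were 1.45 ± 0.08 in aTreg, 1.11 ± 0.01 in rTreg, 1.31 ± 0.05 in Teff and 1.18 ± 0.00 in Tn. All 28 regions lay above rTreg in Foxp3GFPKO, 16 of them past the threshold (camera adjusted p = 6.83e-09, with an estimated correlation adjusted p = 0.0237). All 28 were also higher in aTreg than in rTreg, 15 past the threshold, with a median of 0.36; this set passed with the preset correlation (camera adjusted p = 0.00025) and not with an estimated one (adjusted p = 0.0771). In aTreg against aFoxp3GFPKO 12 X regions were higher and 1 lower (adjusted p = 0.000523 and, with an estimated correlation, adjusted p = 0.0775), and in aTreg against Teff 6 were higher and 0 lower (adjusted p = 0.015 and, with an estimated correlation, adjusted p = 0.161). Teff against Tn (median 0.12, camera adjusted p = 0.0578) and rTreg against Tn (median -0.04, adjusted p = 0.26) did not pass.

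**Figure D5:**
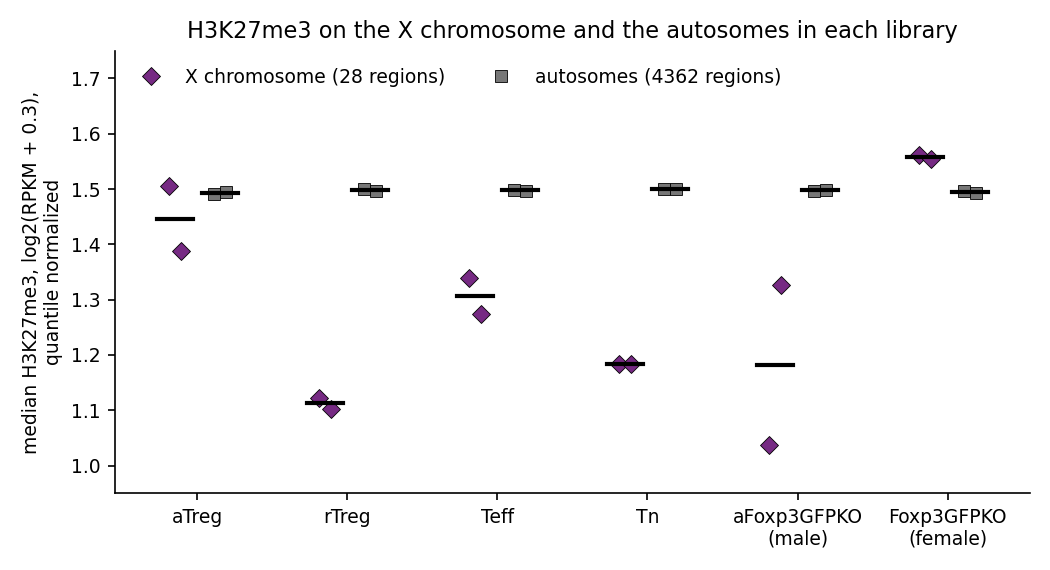
Median H3K27me3 level, as quantile normalized log2(RPKM + 0.3), of the 28 X chromosome regions and of the autosomal regions in each library; points are libraries and bars are means of 2 libraries. Female Foxp3GFPKO cells had the highest X median (1.56) and the male aFoxp3GFPKO libraries differed most from each other.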

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

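The tests against the neighbourhood of Foxp3 sites, against a few regions, and against the starting level for the Foxp3-null cells were chosen only after the result was seen. Every result given here was flagged because a change differed between cell types by a test of the difference itself. Activation changed H3K27me3 differently in Treg cells (aTreg minus rTreg) and in T cells that do not use Foxp3 (Teff minus Tn) at 699 regions. The median of this difference was 0.19 over the 109 Foxp3-overlapping regions and 0.16 over the 28 regions of the X chromosome. The X set passed with the preset correlation (camera adjusted p = 0.00678) and not with an estimated one (adjusted p = 0.138), and its excess over other regions, 0.17, ran from 0.10 to 0.23 with 1 library left out. Set against the change between Foxp3-null groups (aFoxp3GFPKO minus Foxp3GFPKO), the Treg change differed at 643 regions, and the median difference was 0.27 over the Foxp3-overlapping regions and 0.65 over the X chromosome. By Dixon's ratio, the median enrichment of no Foxp3 replicate was flagged (ratio 0.671).

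The first pattern weighed was the gain of H3K27me3 in Foxp3-overlapping regions of activated Treg cells (median 0.44). These regions started low, and a low region has more room to rise once all libraries are forced to 1 distribution. Non-overlapping regions matched on length and on the level in Tn did rise, by a median of 0.21. Of 10000 such draws 0% rose as much. The rTreg level itself and entry of regions into the table through aTreg were not matched, so a part played by them was not excluded. Cyclic loess lowered the excess over other regions from 0.44 to 0.22. A few regions or the X chromosome did not carry the gain, since 65.1% of the overlapping regions were higher against 25.6% of others, and none lies on the X. Matched draws from within 100 kb of a site had a median of 0.23, and 0% of 10000 reached the observed median. Of the regions drawn from, 1173 lay 10 to 100 kb from a site and 169 within 10 kb. The draws thus cannot exclude a neighbourhood effect that fades over shorter distances. A gain linked to Foxp3 occupancy stays a hypothesis, found and weighed on the same data. Foxp3 signal did not track the change (Spearman 0.05, adjusted permutation p = 0.79). Replicates shared the ranking of sites only in part (Spearman 0.05 to 0.63), so a link with binding strength could have been missed. The overlapping regions also gained the mark between the groups without Foxp3 protein (median 0.21). A gene's own response to activation at the places Foxp3 binds would give such a gain as well.

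The second pattern was the smaller gain of the same regions in cells that lack Foxp3 protein (median 0.21 in aFoxp3GFPKO against Foxp3GFPKO). Low level in Tn and region length alone did not account for the difference, as 0% of 10000 draws matched on these reached 0.27. The rTreg level and entry of regions through aTreg were not matched, so a part played by them was not excluded. The median difference was 0.49 in the 59 overlapping regions of low mean level, against 0.14 in other low regions. In the remaining 50 overlapping regions it was 0.01, against -0.05. With low regions left out, the set no longer passed (excess 0.06, camera adjusted p = 0.104). A generally weaker activation response did fit. Among non-overlapping regions matched on their change in Treg cells, 96.33% of draws had a Foxp3-null change as low as that of the overlapping regions. The change of the overlapping regions was thus not reduced relative to the regions drawn. Once the overall slope between the changes (0.41) was taken off, the overlapping regions were left at 0.01, with a bootstrap interval of -0.04 to 0.06. For T cells the slope was 0.51, and the overlapping regions were left at -0.06, with a bootstrap interval of -0.19 to -0.01. A low slope also arises when changes are shared only in part (r = 0.59 for the Foxp3-null groups). The slope thus cannot show a smaller response over the whole genome in Foxp3-null cells, which the normalization could also hide. Nor can the draws decide whether Foxp3 is needed at its own sites. Their regions were picked by an observed Treg change, which favours changes that noise enlarged. A lower Foxp3-null change of the regions drawn could follow from that alone. How far the male and female groups differ in activation stays open.

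The third pattern was on the X chromosome. Between the Foxp3-null groups, 25 of 28 X regions were lower in males, whose X is not inactivated. Activation may differ between the same groups, so sex was not tested apart from it. The rise of all 28 X regions from rTreg to aTreg could come from a different mix of sexes among the donors, which the labels do not give, or from activation, as on the autosomes. Across X regions that change had a Spearman correlation of -0.32 with the female minus male change, with a bootstrap interval of -0.7 to 0.09, and -0.63 across autosomal regions. The explanations cannot be told apart, since the female minus male change may also hold the opposite of an activation step.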

How the results depend on the processing

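Robust variance, autosomes alone and leaving out regions with a mean above 4 were chosen only after the result was seen. The gain of the Foxp3-overlapping set in aTreg against rTreg, in aTreg against aFoxp3GFPKO and in aFoxp3GFPKO against Foxp3GFPKO kept its direction and its call under every alternative. The stricter overlap picked the same 109 regions, so its outcome was fixed. Autosomes alone left the set whole, as 0 of its regions lie on the X. For aTreg against rTreg the excess over other regions was 0.44 and ranged from 0.19 to 0.45, the lowest being without the lowest 25% of regions, and from 0.42 to 0.49 with 1 library left out. No set or named region with a call changed sign. The top 25% of Foxp3 signal in rTreg against Tn, never called, went from 0.03 to -0.05 without the lowest 25% of regions. The balance of calls did turn there, as in aTreg against aFoxp3GFPKO, from 924 higher and 902 lower to 482 and 725. A larger pseudocount, no variance trend, median centring, the replicate block and the added settings changed no call of a set. The scalings moved the share of higher regions by less than 10 points. Cyclic loess, which evens out trends with level, lowered the excess of the overlapping set to 0.22 in aTreg against rTreg, 0.13 in aTreg against aFoxp3GFPKO and 0.12 in aTreg against Teff, and to 0.07 and 0.08 in the differences from T cell and Foxp3-null activation, all with calls kept. Of 180 pairs of a named region and a comparison, 28 lost their call at least once, 105 times in 3878 refits, and 0 reversed. Median Foxp3 enrichment was 1.36 to 1.87 with 1 replicate left out and 2.02 in the strongest 50% of sites.

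Without the lowest 25% of regions, 1572 regions passed in aTreg against rTreg, 517 in aTreg against Teff, 1207 in aTreg against aFoxp3GFPKO, 709 in aFoxp3GFPKO against Foxp3GFPKO, and 372 and 302 in the differences from T cell and from Foxp3-null activation. Fewer regions were tested, and 59 of the 109 overlapping ones were gone. The excess of the overlapping set was then 0.14 in aTreg against Teff (adjusted p = 0.107), and 0.05 (adjusted p = 0.0906) and 0.06 (adjusted p = 0.104) in those differences, with calls lost. The top 25% of Foxp3 signal lost its call in each comparison where it had one, with 0.05 in aTreg against rTreg, 0.07 in Teff against Tn, 0.11 in aTreg against Teff, 0.23 in aTreg against aFoxp3GFPKO, 0.07 in aFoxp3GFPKO against Foxp3GFPKO, and 0.13 and 0.08 in those differences (adjusted p from 0.28 to 0.456), and the X chromosome gained a call at 0.17 in Teff against Tn; the cause was not tested.

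With only the libraries of the groups compared, which leaves fewer samples, 653 regions passed in aTreg against Teff, 1198 in aTreg against aFoxp3GFPKO, 662 in rTreg against Foxp3GFPKO, 407 in aFoxp3GFPKO against Foxp3GFPKO and 279 in the difference from Foxp3-null activation. The order of comparisons by count changed too, with 2105 in Teff against Tn, 1979 in aTreg against rTreg and 481 in rTreg against Tn. At an adjusted p under 0.1 the counts were 679 in rTreg against Tn, and 1057 and 1056 in the differences from T cell and Foxp3-null activation. With an estimated correlation the overlapping set lost its call in Teff against Tn (0.09, adjusted p = 0.0705), and the X chromosome in aTreg against rTreg (0.36), Teff (0.12) and aFoxp3GFPKO (0.31) and in the difference from T cell activation (0.17). With fry, which tests a set against no change and not against other regions, p fell under the threshold for the overlapping set in rTreg against Foxp3GFPKO (excess 0.01) and the X in Teff against Tn (0.12). With cyclic loess the X gained a call in Teff against Tn (0.15). The cause was not tested.

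With each library left out in turn, the group left with 1 library being assumed to vary like the others, counts ran from 863 to 1684 in Teff against Tn, 624 to 1136 in aTreg against Teff, 72 to 471 in rTreg against Tn, 588 to 1284 in rTreg against Foxp3GFPKO, 416 to 1184 in aFoxp3GFPKO against Foxp3GFPKO, and 258 to 739 and 261 to 659 in the differences from T cell and Foxp3-null activation. X medians over other regions ran from 0.11 to 0.16 in Teff against Tn and 0.12 to 0.18 in aTreg against Teff. The call in aTreg against Teff was lost without aTreg replicate 1 (adjusted p = 0.0665), and 1 in Teff against Tn was gained without Tn replicate 2 (adjusted p = 0.0419) or either Foxp3GFPKO replicate (0.0477 and 0.0478). Technical replicates of Foxp3 alone, a count model and the gene lists were not run, for want of separate columns, counts and mm9 gene positions. Foxp3 depth, a median of 6 to 13 reads per site, limits the ranking of sites by strength.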

Other observations

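The counts of regions set apart from all other groups, the splits of groups, the breadth classes, the neighbour pairs and the draws for the T cells were chosen only after the result was seen. Activation changes were shared in part between cell types. Across regions, the change between Foxp3-null groups correlated with the Treg change at r = 0.59 and with the T cell change at r = 0.61, and 418 and 331 regions were higher in both, where independent lists would share 146 and 99.4. In 130 regions aTreg, Teff and aFoxp3GFPKO each lay above rTreg, Tn and Foxp3GFPKO, 18 of them Foxp3-overlapping (Fisher's exact test, adjusted p = 4.89e-09). In 87 they lay below, 1 of them overlapping. A region on chromosome 11 at 99250001-99315001 was among the latter, with 0.62 in aTreg, 0.82 in Teff and 0.93 in aFoxp3GFPKO. It stood at 1.43 to 1.50 in rTreg, Tn and Foxp3GFPKO.

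Activated Treg cells had the most regions set apart from all other groups. In 286 regions they lay above each of the other groups, and 43 of these overlapped a Foxp3 site (Fisher's exact test, adjusted p = 2.77e-23). In 218 they lay below, 4 of them overlapping. These counts can be too high, since the aTreg replicates differed most from each other and the fit shared 1 variance per region over all groups. With only the libraries compared, aTreg against Teff fell from 1112 to 653 regions, and aTreg against aFoxp3GFPKO from 1826 to 1198. Entry of regions into the table through aTreg was not accounted for either. Neighbouring regions are not independent, so p-values from Fisher's exact test can be too small. For other groups the regions above all others numbered 27 to 57, and in Tn 6 of 43 overlapped a Foxp3 site (Fisher's exact test against other regions, adjusted p = 0.00177); these shares were not compared with each other. Few regions separated Treg cells of both states from the rest, 9 higher and 5 lower. A pair of neighbours on chromosome 7 belonged to the former: 121605001-121640001, which holds a Foxp3 site, with 1.37 in aTreg and 1.35 in rTreg against 0.38 to 0.59 elsewhere, and 121555001-121570001 with 1.90 and 1.55 against 0.59 to 0.85.

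Both Foxp3-null groups stood apart from the rest at 40 regions that were higher and 35 that were lower, none of which overlapped a Foxp3 site (Fisher's exact test, adjusted p = 0.626 and 1, against 2.48% of all regions). On the X chromosome at 166410001-166435001 aFoxp3GFPKO reached 3.38 ± 0.41 (SD, n = 2) and Foxp3GFPKO 2.69 ± 0.92, against 0.98 to 1.10 elsewhere, and on chromosome 9 at 3000001-3010001 they reached 4.55 ± 0.18 and 4.42 against 2.08 to 3.10. On chromosome 4 at 3850001-3865001 they were lower, at 1.54 and 1.80 against 2.56 to 2.92. The labels do not give the strains of the groups, so that differences in copy number between strains were not tested.

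Draws matched on the Treg change were also run for the T cells: the Teff minus Tn median of overlapping regions, 0.08, lay below the matched 0.15, with 0.66% of draws as low. In Foxp3-null cells the observed 0.21 lay above the matched 0.16, and 96.33% of such draws were as low. Whether these cell types differ in this respect was not tested.

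Regions within 50 kb of each other changed together in aTreg against rTreg (r = 0.55 over 1164 pairs), while neighbours more than 1 Mb apart hardly did (r = 0.06 over 567 pairs), so that regions are not independent units. Regions over 50 kb had median activation changes of -0.22 in Treg cells, -0.17 in T cells and -0.14 in Foxp3-null cells, with 49.1%, 36.1% and 22.7% called lower and 12%, 15.3% and 8.8% called higher; no set test of breadth was run.

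One region exceeds what the unit allows. The region on chromosome 17 at 39980001-39990001 stood at 16.875 in all 12 libraries, which as RPKM would imply 1202000 RPM. One on chromosome 2 at 98500001-98510001 stood at 10.53 in all. Both held the same rank in every library, so quantile normalization gave them the same value. The region on chromosome 11 at 3030001-3100001, by contrast, ranged from 3.048 to 7.74, and at such high ranks a step of 1 rank can be large. Leaving out the 5 regions with a mean above 4 changed no call of a set.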
